A study of Zea mays with 6 samples.

How the data were processed

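Total RNA of maize anthers, 3 WT and 3 zmrpn1 samples, was extracted with a plant RNA kit, treated with DNase I and made into libraries with a NEBNext Ultra II RNA kit, per the labels' protocols. Whether poly(A) selection or ribosomal RNA removal was used, and whether reads were counted by strand, is not given in the sources used here, so genes that overlap on opposite strands may share counts. The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 1.6.4, StringTie 1.3.6 and DESeq2, with the B73 RefGen_v4 build, and give no settings. The deposited values are whole-number counts per gene for 46430 genes in 6 libraries, with no normalization, and 33193 genes had a count in some library. No row counted unassigned reads. Columns were matched to samples by the genotype code and replicate number in their names.

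The rows comprised 44146 nuclear genes with Zm00001d identifiers, 1765 genes with ENSRNA identifiers, 208 mitochondrial genes, 157 plastid genes and 154 microRNA precursors. Names came from a reference gene table for the assembly Zm-B73-REFERENCE-NAM-5.0, which is another build, so it was used for names and gene order and none of its coordinates are given. It matched all 208 mitochondrial and 157 plastid identifiers and 153 of the 154 precursors, and 0 of the Zm00001d and ENSRNA identifiers. The 25 gene lists fixed before the data were examined, which covered anther wall development, meiosis, pollen wall, ribosome assembly, hormones, stress and markers of other tissues, therefore had 0 members with a name and gave no result. In their place 5 lists of organelle genes were made from the names that did match, after the identifiers and values had been seen.

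Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10), which left 23477, libraries were scaled by TMM, and a quasi-likelihood F test with robust dispersion compared zmrpn1 with WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 changes were the change divided by the square root of F. CPM values use the TMM-scaled library sizes, and shares of mitochondrial and plastid counts use the plain totals. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists. The common biological coefficient of variation was 5.16%. The rule for named genes took up to 8 rises and 8 falls with a reference name, called, at an average of at least 1 log2 CPM and with groups that did not overlap, which left rrn18 and rrn26. Without names it took the 2 identifiers with the largest rise and the 2 with the largest fall under the same filters. The parts of the rule that drew on the 25 lists gave no gene.

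Library totals ran from 16203290 to 29515176 counts. On counts simulated from the means and totals of these libraries for 23289 genes, the zmrpn1 against WT test recovered 62 of 100 genes changed 1.25-fold and 96 of 100 changed 2-fold, with 6 false calls. The changed genes all averaged at least 1 CPM, no other gene was changed, and the simulated spread depended on expression level and not on the gene. Recovery in the real data, where many more genes were called, may therefore differ. Chi-square tests of counts between libraries of a group gave 2.03 to 4.87 per degree of freedom, so no pair agreed within sampling noise and each was counted as 1 replicate. The labels give no sequencing batch or date.

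Clustering of called genes was measured in windows of 50 tested genes along the order of the count table, with 1000 seeded shuffles of the calls. Shares per chromosome were not computed because the count table gives no chromosome. Genes detected in 1 group only needed 0 counts in every library of the other group and at least 10 in each of its own. Intervals on ratios of counts are exact binomial 95% intervals. Alternatives tried were other scalings (library size only, upper quartile, DESeq2 size factors), other tests (DESeq2 1.42.0, limma-voom), other filters and thresholds, the replicate number as a block, each library left out in turn, other window sizes, an estimated correlation and fry for the lists.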

Results

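RNA-seq was carried out on anthers of maize (Zea mays) labelled as stages S3 to S5, from wild-type (WT) plants and from plants of the zmrpn1 genotype. The sample titles of the zmrpn1 group name Mutator, a family of maize transposable elements used to make insertion mutants, and the genotype is given as a knockout of ZmRPN1. Each group had 3 libraries. The series title ties the gene to the quantity of pollen, and the comparison asks which transcripts differ in abundance between mutant and wild-type anthers. The WT libraries held 20457510, 16203290 and 29515176 counts, and the zmrpn1 libraries held 18724037, 20824288 and 26000578 counts. The 10 most abundant genes took between 2.51% and 2.74% of the counts of a library. Pearson correlations of log2 CPM (counts scaled to library size) across genes were 0.992 to 0.993 within groups and 0.979 to 0.982 between groups. The first principal component held 58.5% of the variance and parted the genotypes, and the second held 11.6%. The labels give no gene identifier for ZmRPN1 and no reference name pointed to it, so the abundance of the targeted gene in each library was not analysed here and the genotype labels were not checked against it.

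Anthers of zmrpn1 differed from WT anthers in many genes, most of them by small amounts. Of 23477 tested genes, 1556 were higher and 1366 were lower in zmrpn1 at a Benjamini-Hochberg adjusted p under 0.05 (edgeR quasi-likelihood test, n = 3 and 3), which is 12.45% of the tested genes. The median absolute change of these 2922 genes was 0.46 on the log2 scale, and 1573 of them changed by less than 0.5 log2 units. The median change of all tested genes was 0.00122 log2 units. In 2831 of the 2922 genes the 3 zmrpn1 libraries lay on one side of the 3 WT libraries. Over all tested genes 27.0% did so, where chance gives 10% for 3 against 3. DESeq2 called 2147 genes, of which 2074 were also called by edgeR, all in the same direction. The small excess of higher genes was not stable: 1069 were higher and 1078 lower with DESeq2, 1307 and 1339 without zmrpn1 replicate 3, 1263 and 1260 without WT replicate 3, and 1719 and 1273 with scaling by library size only. The labels do not say whether the libraries of a group came from separate plants or pools, nor whether the WT plants were siblings of the mutants, so p-values measure the spread between these libraries.

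The direction of change depended on its size, and the largest changes were falls in zmrpn1. Below 0.5 log2 units 864 genes were higher and 709 were lower, and from 0.5 to 1 log2 unit 439 were higher and 267 were lower. From 1 to 2 log2 units the numbers were 222 and 239. From 2 to 4 log2 units 31 genes were higher and 121 were lower, and 30 genes fell by 4 log2 units or more while 0 rose by that much. Together 151 of the 182 genes that changed by at least 2 log2 units were lower in zmrpn1, or 83.0%. The counts of such genes rose to 75 higher and 241 lower when genes with low counts were also tested, and 49 were higher without WT replicate 3. They fell to 24 higher and 103 lower when genes were filtered at 1 CPM in 3 libraries.

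**Figure D1:**
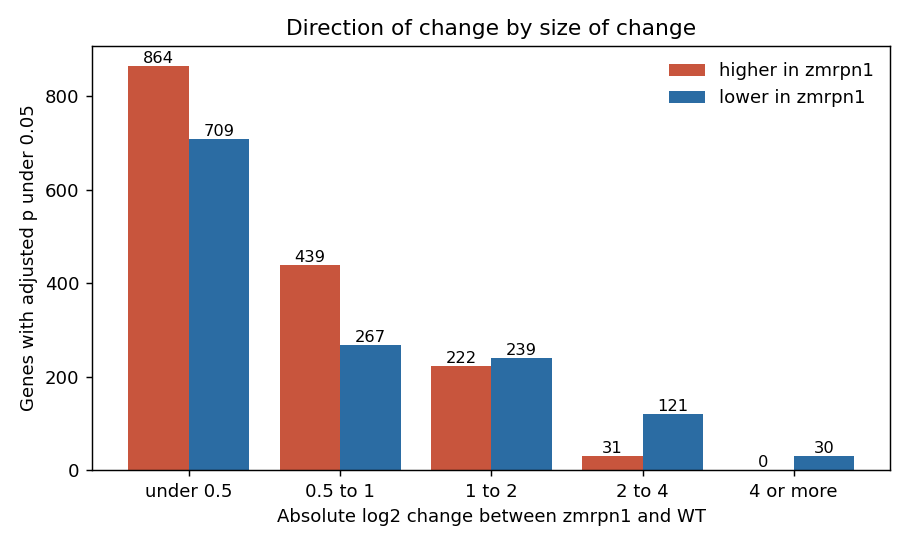
Bars show the number of genes higher (red) and lower (blue) in zmrpn1 than in WT at an adjusted p under 0.05, by absolute log2 change on the x axis. Higher genes outnumber lower genes below 1 log2 unit (864 against 709, then 439 against 267), and lower genes outnumber higher genes above 2 log2 units (121 against 31, then 30 against 0).

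The furthest changed nuclear genes were taken among genes of at least 1 log2 CPM on average whose groups did not overlap. The rises started from low expression in WT, and the falls ended near absence in zmrpn1. The count table and the reference table do not pair nuclear identifiers with gene names, so these genes are given by identifier only. Zm00001d007286 rose from 0.655 ± 0.138 CPM in WT to 8.19 ± 0.175 CPM in zmrpn1 (mean ± SD, n = 3), a log2 change of 3.58 with a standard error of 0.20 (edgeR adjusted p = 7.46e-17). Zm00001d021759 rose from 0.349 ± 0.0794 to 4.25 ± 0.679 CPM, a log2 change of 3.54 with a standard error of 0.28 (edgeR adjusted p = 1.04e-12). The WT libraries held 45 counts of Zm00001d007286 and 24 of Zm00001d021759, against 539 and 283 in the zmrpn1 libraries. Zm00001d022084 fell from 17.5 ± 0.890 to 0.0481 ± 0.0535 CPM (edgeR adjusted p = 1.29e-24). It had 1151 counts over the WT libraries and 3 over the zmrpn1 libraries, a ratio of 380 scaled by library totals (95% exact interval 129.7 to 1846). Without zmrpn1 replicate 1, which held 2 of the 3 counts, the ratio was 814 (95% exact interval 146 to 32200). Zm00001d037656 fell from 14.4 ± 2.16 to 0.0515 ± 0.0891 CPM (edgeR adjusted p = 2.39e-20), with 925 counts against 4 and a ratio of 229 (95% exact interval 89.2 to 842). All 4 counts lay in zmrpn1 replicate 3. Without that library the ratio to a floor of 3 counts over the remaining zmrpn1 libraries was 184. The exact 95% lower limit was 150. All 4 changes kept their direction and an adjusted p under 0.05 in each of the 15 alternative fits.

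**Figure D2:**
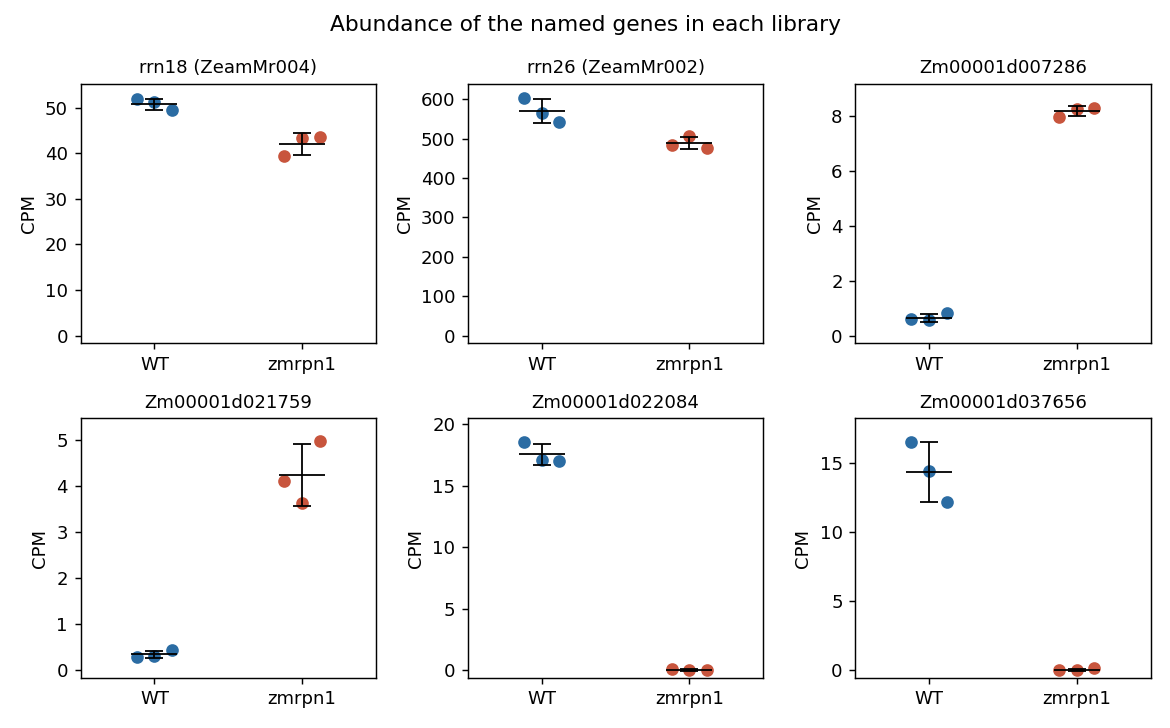
Points show the CPM of each library in WT (blue) and zmrpn1 (red) for 2 mitochondrial ribosomal RNAs and 4 nuclear genes, with the mean and SD of 3 libraries as lines, each panel on its own linear axis from 0. The groups do not overlap in any panel, and Zm00001d022084 and Zm00001d037656 lie near 0 in zmrpn1 (means of 0.0481 and 0.0515 CPM).

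Some genes with counts in every WT library had none in zmrpn1. With at least 10 counts in each WT library and 0 in each zmrpn1 library there were 2 such genes, and 0 genes showed the opposite pattern. Both are named here after their values were seen. Zm00001d024208 had 38, 26 and 51 counts in the WT libraries and was at least 38.0-fold lower in zmrpn1 (edgeR adjusted p = 1.81e-10). Zm00001d053554 had 23, 14 and 34 counts and was at least 23.4-fold lower (edgeR adjusted p = 4.39e-08). These bounds set 3 counts over the zmrpn1 libraries against the WT total and, like the intervals on count ratios, cover counting error only. The number of genes at 0 in zmrpn1 was 9 with a minimum of 5 counts and 1 with a minimum of 20 counts, and 4, 6 and 6 without WT replicate 2, zmrpn1 replicate 2 and zmrpn1 replicate 3. Without zmrpn1 replicate 1, 1 gene was at 0 in WT alone.

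Both tested mitochondrial ribosomal RNAs were lower in zmrpn1. The rrn26 gene (ZeamMr002), which encodes the large-subunit ribosomal RNA of the mitochondrion, fell from 570 ± 30.1 to 489 ± 15.7 CPM (mean ± SD, n = 3), a log2 change of -0.22 with a standard error of 0.05 (edgeR adjusted p = 0.0024). The rrn18 gene (ZeamMr004), which encodes the small-subunit ribosomal RNA, fell from 50.8 ± 1.21 to 42.1 ± 2.43 CPM, a log2 change of -0.27 with a standard error of 0.06 (edgeR adjusted p = 0.00191). All 3 zmrpn1 libraries lay below all 3 WT libraries for both genes. Mitochondrial genes as a whole took 720 ± 25.6 CPM, by plain library totals, in WT and 628 ± 13.1 in zmrpn1 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Most of this difference lay in the same ribosomal RNAs, which took 617 ± 27.3 CPM in WT and 533 ± 17.3 in zmrpn1. All other mitochondrial genes took 102 ± 1.84 CPM in WT and 95.1 ± 4.16 in zmrpn1 (two-sided exact permutation p = 0.1 for each part). The ribosomal RNAs already held 617 of the 720 CPM in WT. An equal fall of all mitochondrial RNA would therefore also place most of the difference in them. These shares were computed after the gene results had been seen. Plastid genes took 29.5 ± 3.8 CPM in WT and 33.7 ± 2.64 in zmrpn1 (two-sided exact permutation p = 0.2). Whether the counting divided reads between these ribosomal RNA genes and near-identical copies elsewhere in the genome is not given in the sources used here, so their levels are uncertain to that extent.

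Protein-coding genes of the mitochondrion had mostly negative values, but no list of organelle genes passed the camera test on all 6 libraries with TMM scaling and no replicate block. These lists were drawn up after the identifiers and values had been seen. The 7 tested genes for subunits of the respiratory chain and ATP synthase and for cytochrome c maturation, among them nad4, cox1 and atp4, all had negative log2 values with a median of -0.32 (camera adjusted p = 0.0627; adjusted p = 0.271 with an estimated correlation). The log2 value of nad4, a subunit of respiratory complex I, was -0.43 with a standard error of 0.21 (edgeR adjusted p = 0.227), and that of cox1, a subunit of cytochrome c oxidase, was -0.32 with a standard error of 0.24 (edgeR adjusted p = 0.481). Of 5 tested mitochondrial ribosomal protein genes 4 had negative values, and of 15 open reading frames and the maturase gene 11 did (camera adjusted p = 0.265 for both lists; adjusted p = 0.408 with an estimated correlation). Of 12 tested plastid genes 10 had positive values, or 11 when scaled by library size alone, with a median of 0.31 (camera adjusted p = 0.0838; adjusted p = 0.292 with an estimated correlation). None of these 39 genes was called by edgeR, DESeq2 or limma-voom, and 1 had an unadjusted edgeR p under 0.05. The respiratory list passed the threshold with scaling by library size only (camera adjusted p = 0.0481) and without WT replicate 1 (0.0244), WT replicate 2 (0.0324) or zmrpn1 replicate 1 (0.0467), and the plastid list without WT replicate 3 (0.0476). With an estimated correlation the adjusted p was 0.244, 0.263, 0.289 and 0.273 for the respiratory list and 0.249 for the plastid list in the same fits. That form of the test has little power here, since it uses only the few residual degrees of freedom of 6 libraries. The estimated correlation of the respiratory list, with all 6 libraries and TMM scaling, was -0.0827, below the preset 0.01. The test with an estimated correlation therefore does not decide whether these calls hold. With the preset correlation the respiratory list did not pass with limma-voom (camera adjusted p = 0.341), DESeq2 (0.63) or low-count genes included (0.16). Nor did it pass without WT replicate 3 (0.0792), zmrpn1 replicate 2 (0.0508) or zmrpn1 replicate 3 (0.0695).

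A small part of the genes that differed between zmrpn1 and WT was crowded in a few stretches of the count table. The row order of the table followed the order within chromosomes as far as named genes could show. In all 142 pairs of neighbouring microRNA precursors on one chromosome, the order of the rows was the order in the reference assembly. Another 10 neighbouring pairs lay on different chromosomes and do not check the order, so a misplaced row could escape it. A window of 50 neighbouring tested genes held up to 22 called genes, against a median of 16 and a highest value of 20 for the fullest window in 1000 shuffles (one-sided permutation p = 0.001, the smallest the shuffles can give). For called genes that changed by at least 1 log2 unit the fullest window held 13, against a median of 7 and a highest value of 10 (one-sided permutation p = 0.001). It lay between the precursors MIR160c and MIR166a.

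Windows above the 95th percentile of the shuffles, 18 called genes, made up 4 stretches. Together the stretches held 91 called genes, and 2831 lay elsewhere. The stretch from Zm00001d003227 to Zm00001d003313, between the precursors MIR156e and MIR2118b, held 19 called genes of 51 tested, 9 higher and 10 lower in zmrpn1. A pair of stretches between MIR169k and MIR1432 held 29 called genes of 83 (Zm00001d021621 to Zm00001d021746, 19 higher and 10 lower) and 20 of 55 (Zm00001d021755 to Zm00001d021845, 13 higher and 7 lower). Zm00001d021759, with its log2 rise of 3.54, belongs to the latter. The pair lies close together by identifier and may form the same region. The stretch from Zm00001d035295 to Zm00001d035526, between MIR160c and MIR166a, held 23 called genes of 75, of which 5 were higher and 18 were lower in zmrpn1. Its excess of lower genes over called genes elsewhere passed a two-sided Fisher's exact test (adjusted p = 0.0108 over the 4 stretches), and the other 3 stretches gave adjusted p of 0.392 to 0.65. The test treats neighbouring genes as independent, which linked genes may not be. The end genes only mark positions and were not chosen for their own change.

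**Figure D3:**
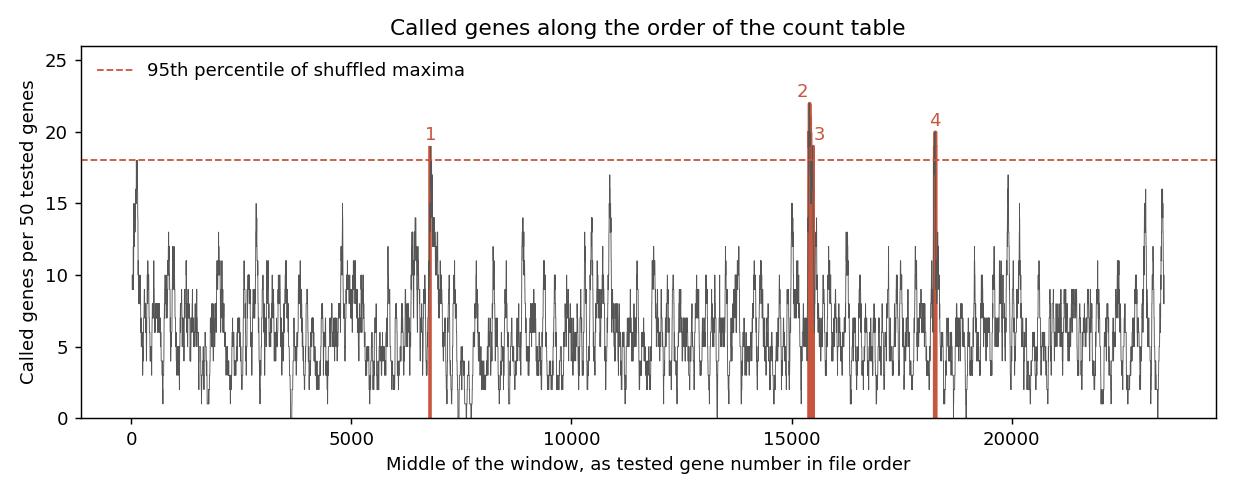
The line gives the number of called genes in each window of 50 neighbouring tested genes, by position in the order of the count table, and the dashed line marks 18 called genes, the 95th percentile of the fullest windows in shuffles. The 4 shaded stretches hold the windows above that line, with up to 22 called genes.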

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

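The counts of genes changed by at least 2 log2 units, the organelle list tests, the share of variance on the first component and the window counts under other orders, calls and fits were chosen after the results were seen. The direction and side of the threshold of rrn18, rrn26 and the 4 named nuclear genes held in all 15 alternative fits (rrn18 adjusted p 0.000579 to 0.0296, rrn26 0.000134 to 0.0355), and the fullest window kept a permutation p of 0.001 to 0.008 in 21 alternatives. Requiring at least 1 log2 unit left 253 genes higher and 390 lower, and an adjusted p under 0.01 left 1011 higher, both by construction. Testing genes with low counts gave 75 higher and 241 lower by at least 2 log2 units and a first component of 39.9%. A filter at 1 CPM gave 24 higher and 103 lower by at least 2 log2 units and a first component of 64.1%. Genes at 0 in zmrpn1 alone numbered 9 with a minimum of 5 counts and 1 with a minimum of 20. Leaving out 1 library gave 1184 to 1421 genes higher and 1033 to 1339 lower, 32 to 49 higher and 149 to 184 lower by at least 2 log2 units, 2 to 6 at 0 in zmrpn1 alone, 0 to 1 at 0 in WT alone, 58.8% to 60.4% on the first component and fullest windows of 18 to 22. It gave adjusted p of 0.0244 to 0.0792 for the respiratory list and 0.0476 to 0.165 for the plastid list. The respiratory list reached 0.0481 with library size only (adjusted p = 0.244 with an estimated correlation) and 0.63 with DESeq2, whose tested genes may differ. It reached 0.0481 with fry, which tests if list genes move one way, not against other genes. Over all its alternatives it ran from 0.00592 to 0.63, and the plastid list from 0.0198 to 0.63. With the replicate number as a block, 3005 genes were called, the respiratory list reached 0.0081 and the plastid list 0.0198, and with the replicate block and library size only they reached 0.00592 and 0.0285. With an estimated correlation the adjusted p was 0.346 and 0.388 with the block, and 0.328 and 0.421 with the block and library size only. That form of the test uses only the few residual degrees of freedom and has little power, so it does not decide whether these calls hold. Over all fits with an estimated correlation the respiratory list gave 0.244 to 0.378 and the plastid list 0.249 to 0.572. With the block, neither the direction nor the side of the threshold changed for the named genes, the other lists and the fullest window. The remaining results were not refitted with the block. The numbers did not pair the libraries, since deviations of same-numbered libraries correlated at -0.037, 0.02 and 0.031. The cause of the changes in the list tests was not tested. Mitochondrial ribosomal proteins had too few tested members at 1 CPM for a value. Leaving out a replicate number in both groups (none stood apart) and lists without shared members (none were shared) were not run. At the depth, spread and number of these libraries, 62 of 100 genes with the smaller simulated change were recovered, against 96 of 100 with the 2-fold change.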

Other observations

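The tests of neighbouring large falls, of chance placement and of larger changes inside the crowded stretches, and of the other mitochondrial genes and their ratio to ribosomal RNA were chosen after the results were seen, as were the descriptions by expression level and of genes with ENSRNA identifiers. The share of genes that differed between zmrpn1 and WT was similar at all levels of expression, at 11.5%, 13.5%, 12.2% and 12.6% in 4 equal classes of tested genes from the lowest to the highest average CPM. The size of change of called genes was not similar. The median absolute log2 change of called genes was 1.21, 0.508, 0.308 and 0.251 in the same classes. Small changes are harder to call in weakly expressed genes. The medians and shares of called genes therefore do not show how the size or frequency of change depended on expression level.

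Genes with ENSRNA identifiers gave 3 called genes of 69 tested (edgeR), named here after their values were seen. ENSRNA049479819 rose by 0.39 log2 units (standard error 0.07, adjusted p = 3.6e-05) and ENSRNA049479595 rose by 0.54 (standard error 0.18, adjusted p = 0.0439), while ENSRNA049478201 changed by -0.33 (standard error 0.10, adjusted p = 0.037). Libraries of one group differed by more than 4-fold in 6 of 21 such genes with a mean of at least 2 CPM (28.6%), against 8 of 19946 nuclear genes with Zm00001d identifiers (0.0401%). ENSRNA049479027, for example, had 91, 125 and 80 counts in the WT libraries and 4, 195 and 180 in the zmrpn1 libraries. All 154 microRNA precursors had 0 counts in every library.

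Other ways of dividing the 6 libraries into 3 and 3 are too few, at 10 splits with the real one, for a share under 0.05. The genotype split gave 2922 called genes and the highest other split gave 1, so 1 of 10 splits reached the real count. For genes changed by at least 2 log2 units the counts were 182 and 1, again reached by 1 of 10 splits. For organelle lists past the threshold the genotype split gave 0 and the highest other split gave 1. A count of 0 is reached by 10 of 10 splits whatever the data, so this count says nothing about chance.

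Changes of at least 2 log2 units were mostly falls in zmrpn1. The choice of scaling was argued against as the cause, since falls made up at least 81.8% of such changes under 3 other scalings. Those scalings left the median log2 change of all tested genes within 0.0131 of 0, so this share could hardly have moved. A scaling error common to all of them was not tested. A candidate explanation is that the zmrpn1 plants carry segments from a parent in which some genes of the B73 reference are missing, silent or too diverged for their reads to be placed: 13 pairs of neighbouring tested genes were both large falls, against a median of 1 and a highest value of 6 in 1000 shuffles (one-sided permutation p = 0.001, the smallest they can give). These falls formed 8 runs of up to 3 genes, 1 of them holding Zm00001d024208, and 12 of the 13 pairs lay outside the 4 crowded stretches, which held 6 of the 151 large falls and 8 of the 31 large rises. Shared control of neighbouring genes, reads shared between tandem copies and an effect of the zmrpn1 mutation itself were not tested and remain open.

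Chance placement of called genes was argued against for the stretch from Zm00001d021621, whose fullest window of 22 called genes was above all 1000 shuffles, and less firmly for the other 3 stretches, whose fullest windows of 20, 19 and 19 were reached by 6, 26 and 26 of the shuffles. Gain or loss of whole copies of a stretch was argued against, since the median log2 change of all tested genes in a stretch lay no further than 0.0686 from 0. A linked segment from another parent, carried along with the mutant allele or retained by chance, may account for the crowding: leaving out the stretch from Zm00001d035295, which had been seen to hold many large changes, 30.9% of called genes inside (21 of 68) changed by at least 1 log2 unit, against 21.5% (609 of 2831) elsewhere, close to the threshold (one-sided Fisher's exact p = 0.0483). The larger changes were uneven, with 1 such gene in the stretch from Zm00001d003227 and 10 in each stretch between MIR169k and MIR1432, which lie close together by identifier. Fisher's test treats neighbouring genes as independent, so its p rests mostly on the same region and cannot weigh this explanation. The position of ZmRPN1 was not used here, so whether a stretch surrounds it was not tested, and local effects of the mutation remain open.

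Whether the fall of rrn18 and rrn26 is part of a lower amount of mitochondrial RNA of every kind in zmrpn1 anthers stays open. The other 27 tested mitochondrial genes had a median log2 value of -0.163 (95% bootstrap interval -0.242 to -0.0473), an interval that just misses the median of -0.244 of the ribosomal RNAs. That interval takes the ribosomal RNA median as fixed, though the values of rrn26 and rrn18 had standard errors of 0.05 and 0.06. All these genes were also measured in the same 6 libraries, so the narrow miss separates nothing. Abundant members of the other 27 genes went both ways, named after their values were seen. The values of orf105-c (0.06, standard error 0.10) and orf101-a (0.09, standard error 0.11) were not negative. Those of rps12 (-0.05, standard error 0.12), orf179 (-0.20, standard error 0.14) and orf140-b (-0.33, standard error 0.15) were. Ribosomal RNA counts per count of all other mitochondrial genes were 6.04 ± 0.373 in WT and 5.62 ± 0.435 in zmrpn1 (n = 3, two-sided exact permutation p = 0.3), so these libraries do not separate an equal fall from a fall of ribosomal RNA alone. A fuller removal of ribosomal RNA from the zmrpn1 libraries stays open too, since plastid ribosomal RNA had only 34 counts in WT and 27 in zmrpn1, a ratio of 0.802 (95% exact interval 0.465 to 1.37). Fewer or different cells in the mutant anthers and an effect of the mutation on mitochondria were not tested.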
